A study of Homo sapiens with 12 samples.

How the data were processed

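RNA of A375 cells, an established human melanoma line, was measured by mRNA sequencing in 12 libraries. The libraries form 4 groups of 3 from 2 factors, OGDH status (WT or OGDH-deficient) and treatment (control or NAC). OGDH encodes the E1 subunit of the 2-oxoglutarate dehydrogenase complex of the tricarboxylic acid (TCA) cycle. All cells were deprived of glucose for 5 h before collection, per the series' design text, so no comparison with fed cells could be made. Sample titles call the OGDH-deficient cells a knockout and the design text calls them a knockdown, so the neutral term OGDH-deficient is used. Sample descriptions and file headers read KD or KDN for these cells and Sc or ScN for the WT cells. These abbreviations are not spelled out, so WT cells may carry a control reagent. NAC is an abbreviation that the labels do not spell out, and its dose and time are not given in the sources used here. The labels say that samples were collected in parallel and not that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

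Per the labels' protocols, total RNA was extracted with Trizol and made into DNBSEQ eukaryotic mRNA libraries. The submitters' processing notes name the hg38 build, Trim Galore, Subread and featureCounts. The deposited table holds whole-number counts per gene symbol, and per the file headers it was made by featureCounts 2.0.6 over exons, without strand, without multi-mapping reads and with both mates of a pair counted singly. A fragment therefore adds up to 2 to a count, so counting intervals are too narrow. Without strand, reads of a gene and of its antisense partner cannot be told apart, and reads shared by near-identical genes are missing. The annotation version is not given in the sources used here. The table lists 61209 symbols, of which 21162 had no count in any library, and 80 symbols lie on several chromosomes, where the deposited counts add different loci. Library totals ran from 31765845 to 37554200 counts.

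Counts were analysed as deposited with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr over the 4 groups were kept, which left 18781 genes holding 99.9% of the counts. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, so that the groups share the spread estimate with 8 residual degrees of freedom. The common biological coefficient of variation was 5.94%. Tests with glmQLFTest compared OGDH-deficient with WT cells in each treatment and NAC with control in each genotype, and tested the interaction, which is the NAC effect in OGDH-deficient cells minus that in WT cells. All p-values for genes are edgeR quasi-likelihood values with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p under 0.05 was called. Levels are CPM, the usual per-library scaling of counts, with TMM-scaled library sizes, given as mean ± SD of 3 libraries, and log2 fold changes are given ± SE. The SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. It rests on the spread estimate that the groups share and can be too small for a group with more spread.

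The design, the alternatives, 42 gene lists and the rule for naming genes were fixed before the data were examined. The rule names OGDH and, for each comparison of 2 groups, genes with an adjusted p under 0.05, a mean CPM of at least 5 and no overlap between the 3 libraries of one group and those of the other. A share of 10% of genes shows no such overlap by chance. Of these, the 7 highest and 7 lowest by log2 fold change and the 4 rising and 4 falling genes with the smallest p were named. For the interaction the 5 highest and 5 lowest were named without the overlap limit, and for each list described up to 4 members with the smallest p. Some genes that this rule names are not reported here, and they still count in the totals over all genes and in the lists. The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), which compares a list with all other genes, with a preset correlation between genes of 0.01 and adjustment over the 42 lists. Members were counted over all genes tested and adjusted over the list alone. Of the 836 listed genes 747 were tested.

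Both sets of fold changes were compared by Pearson correlation over all tested genes, which are not independent replicates. For pairs of comparisons that share libraries, unchanged groups were simulated 20 times to give the correlation and covariance that sharing alone produces. Shares of mitochondrial counts were compared with exact permutation tests, for which 3 against 3 libraries allow no two-sided p below 0.1, and intervals on single libraries are 95% Wilson intervals, which cover counting error only. The 3′ untranslated regions of the GENCODE annotation supplied with the data were searched for words of 7 bases, with a regression of log2 fold change on each word that also held length, GC content and expression.

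The alternatives were RLE scaling, library size without a composition factor, no filter, a stricter filter, DESeq2 1.42.0, a robust spread estimate, the libraries of the comparison alone, the replicate number as a block, a fold limit, mitochondrial genes left out, and each library left out in turn. For lists they also included the correlation estimated from the data and the fry test. Halved counts, and leaving out libraries for the correlations, were added after the data had been seen. Each step was tested on simulated data with known changes. For OGDH-deficient against WT cells without NAC (18339 simulated genes), 59.7% of genes changed by a log2 of 0.5, 92.5% of those changed by 1 and 98.5% of those changed by 2 were recovered, and 5.11% of calls were false. For the interaction (18313 genes) the shares were 44.8%, 83.6% and 98.5%, with 3.82% false. A simulated shift of 0.5 in 1 list was called with the preset and with the estimated correlation. Simulated genes were drawn independently, so this does not show how either test performs on correlated genes. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the word search and the figures.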

Results

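The transcriptome of A375 melanoma cells was measured after 5 h without glucose in WT and OGDH-deficient cells, each with and without NAC. Each of the 4 groups held 3 libraries, with 32654582 to 36987166 counts in WT control cells, 31765845 to 35779056 in WT cells with NAC, 33643448 to 37554200 in OGDH-deficient control cells and 33207449 to 36564571 in OGDH-deficient cells with NAC. The first principal component of log2 CPM (38.8% of the variance) separated the genotypes and the second (21.3%) the treatments. Replicate 2 of the OGDH-deficient cells with NAC stood apart from its group. The variance of its gene counts against replicates 1 and 3 was 11.7 and 20.4 times that of Poisson sampling. The ratio was 2.93 to 6.62 between libraries of the other 3 groups and 5.72 between replicates 1 and 3.

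OGDH, the targeted gene (hg38, chromosome 7, 44606572 to 44709066, plus strand; counts cover all annotated exons), was expressed at 60.9 ± 3.06 CPM in WT control cells and 4.17 ± 0.413 CPM in OGDH-deficient control cells, 6.85% of the WT level (SD, n = 3). With NAC the levels were 49.0 ± 5.00 and 5.93 ± 0.794 CPM, so that 12.1% remained. Every OGDH-deficient library (3.80 to 6.46 CPM) lay below every WT library (43.8 to 63.0 CPM), as the labels state. The log2 fold change was -3.87 ± 0.10 without NAC (edgeR adjusted p = 3.2e-16) and -3.04 ± 0.09 with NAC (adjusted p = 3.39e-15). OGDH fell by 0.31 ± 0.07 with NAC in WT cells and rose by 0.51 ± 0.12 in OGDH-deficient cells.

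**Figure D1:**
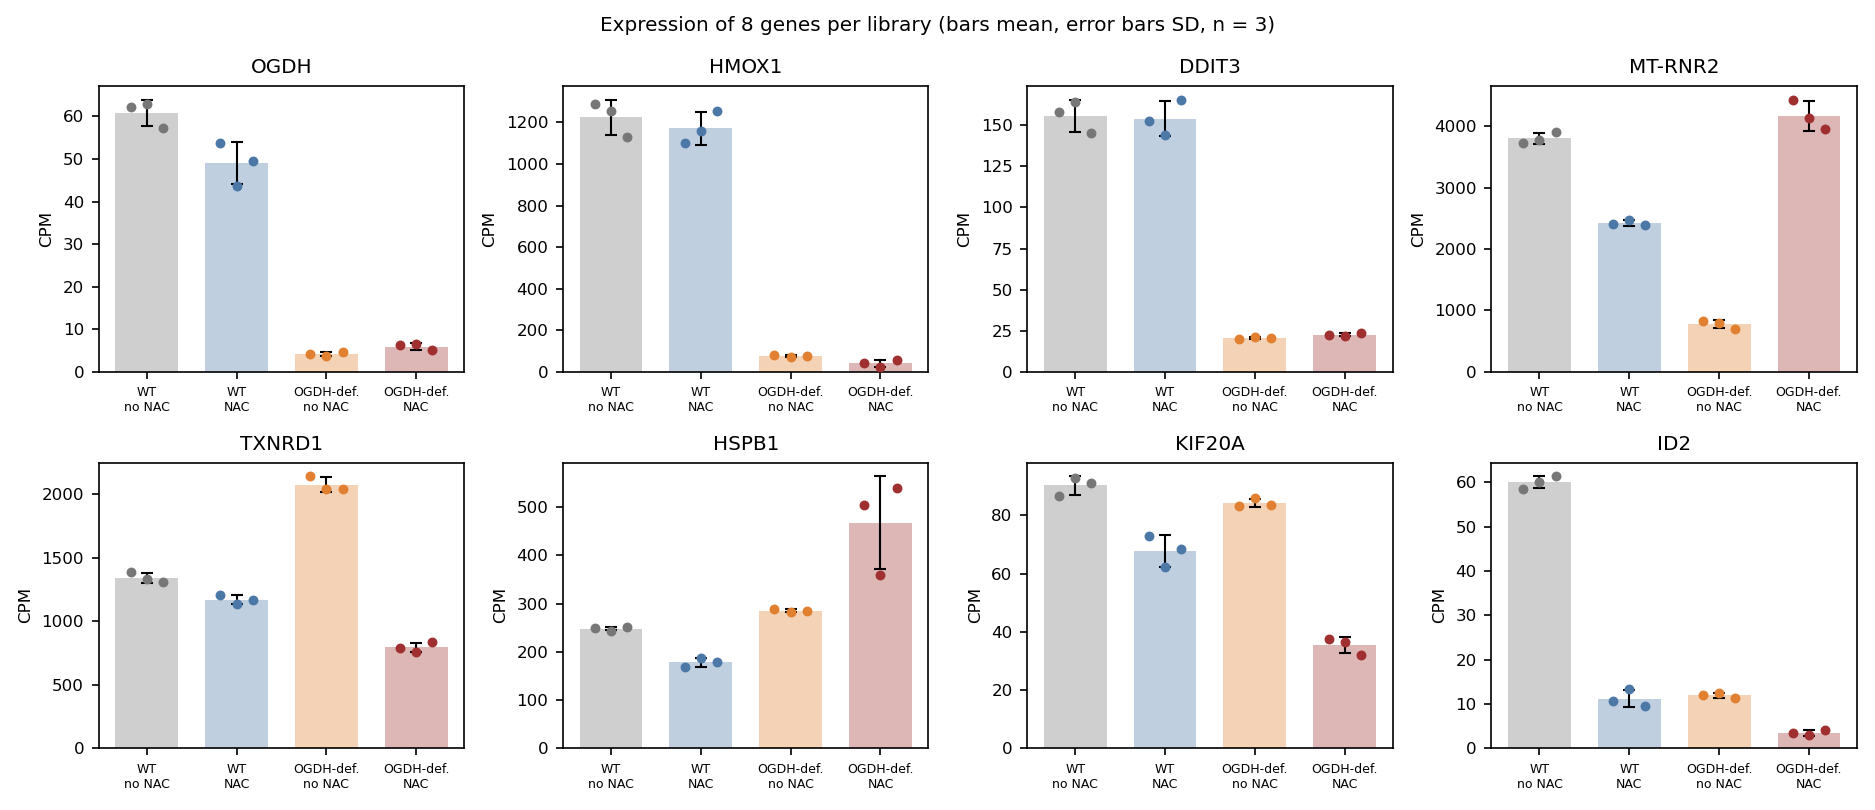
Expression of 8 genes in CPM (linear axes from 0) in WT and OGDH-deficient A375 cells without and with NAC; bars are means, error bars SDs and points the 3 libraries of each group. OGDH, HMOX1 and DDIT3 are low in all OGDH-deficient libraries, MT-RNR2 is low in OGDH-deficient cells without NAC (776.5 CPM) and high with NAC (4173 CPM), and KIF20A is lowest in OGDH-deficient cells with NAC (35.4 CPM).

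The first comparison asked how OGDH-deficient cells differed from WT cells, both deprived of glucose and without NAC. The labels name no other reagent against OGDH and no rescue. Loss of OGDH therefore cannot be told apart from other effects of the reagents or lines used, and OGDH effect below means this difference only. Among the 200 genes raised most, 30% carried the 3′ untranslated word GTGTCAC, against 10.6% of all genes searched, as described under Other observations. Genes of the endoplasmic reticulum (ER) stress response fell: of 20 ER chaperones and related genes, 17 fell and none rose, with a median log2 fold change of -0.64. HERPUD1, which acts in ER-associated degradation, dropped by 2.62 ± 0.05 from 369.3 ± 15.4 to 59.9 ± 2.37 CPM, and the chaperone HSPA5 (BiP) dropped by 1.87 ± 0.06 from 2794 ± 138.0 to 765.8 ± 25.8 CPM (edgeR adjusted p = 1.31e-17 and 1.49e-14, n = 3). XBP1, a transcription factor of the unfolded protein response, fell by 1.64 ± 0.06 and the co-chaperone DNAJB11 by 1.08 ± 0.06. The list differed from other genes (camera adjusted p = 7e-10; adjusted p = 0.276 with an estimated correlation), and 17 members fell when adjusted over the list alone.

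Among called genes with a mean CPM of at least 5, the lowest fold change belonged to HMOX1, the heme oxygenase that breaks down heme (chromosome 22, 35381096 to 35394207), which fell by 3.98 ± 0.17 from 1225 ± 85.0 to 77.5 ± 5.01 CPM (edgeR adjusted p = 5.12e-13). CHAC1, a glutathione-degrading enzyme, fell by 3.77 ± 0.10, DDIT4, an inhibitor of mTORC1 signalling, by 2.93 ± 0.09, and DDIT3 (CHOP), a stress transcription factor, by 2.92 ± 0.06. CHAC1, DDIT4 and DDIT3, but not HMOX1, are listed among ATF4 targets, and that list moved both ways. Of its 34 tested members 18 fell and 12 rose, 19 and 14 when adjusted over the list alone. Among those that rose was the serine synthesis enzyme PSAT1 (0.92 ± 0.04). The ATF4 list was not called here (median -0.27, camera adjusted p = 0.287). PTMA, which encodes prothymosin alpha, fell by 1.87 ± 0.04, and MIR1244-2, whose sequence resembles PTMA and its pseudogenes, by 3.16 ± 0.19. Reads of these near-identical sequences could be split or lost, so both values are uncertain. ZNF469, a zinc finger gene, fell by 2.98 ± 0.25.

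Immediate early genes, which respond within minutes to growth factors and stress, were lower as a group: 15 of 20 fell and 3 rose, over all genes and adjusted over the list alone, with a median of -1.32. The phosphatase DUSP1 fell by 1.35 ± 0.06, the transcription factors JUNB and ATF3 by 1.24 ± 0.06 and 1.44 ± 0.09, and BTG2, an antiproliferative gene, by 2.13 ± 0.12 (edgeR adjusted p at most 7.48e-11). Among the others KLF6 (0.52 ± 0.04) and MYC (0.23 ± 0.05) rose. The camera test gave an adjusted p of 2.83e-05 (adjusted p = 0.439 with an estimated correlation).

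All 13 mRNAs of the mitochondrial genome fell, with a median of -0.84, also when adjusted over the list alone. MT-ND6, a complex I subunit, fell by 3.07 ± 0.20, MT-ND5 by 1.89 ± 0.10, MT-ND1 by 1.63 ± 0.13 and MT-CO1, a subunit of cytochrome c oxidase, by 1.59 ± 0.15 (edgeR adjusted p at most 7.25e-08). The mitochondrial list had a camera adjusted p of 1.14e-06 (adjusted p = 0.439 with an estimated correlation). The large mitochondrial ribosomal RNA, MT-RNR2, fell by 2.29 ± 0.06 from 3802 ± 93.0 to 776.5 ± 68.8 CPM. Nuclear genes of oxidative phosphorylation went the other way: 22 of 38 rose and 2 fell, over all genes and adjusted over the list alone, with a median of 0.17, among them UQCRC1 (0.26 ± 0.04), while the electron carrier CYCS fell by 0.21 ± 0.04. Nuclear genes of the respiratory chain had a camera adjusted p of 0.00101 (adjusted p = 0.784 with an estimated correlation). Mitochondrial transcripts made up 4.01 ± 0.0710% of counts in WT and 2.05 ± 0.145% in OGDH-deficient control cells (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). Nuclear copies of mitochondrial sequence can share reads with these genes.

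Cholesterol synthesis genes, targets of the transcription factor SREBP2, and DNA replication genes were also lower. Of 24 tested cholesterol genes 14 fell and 3 rose, over all genes and over the list alone, with a median of -0.38. They were led by STARD4, which carries cholesterol, at -1.37 ± 0.05, IDI1 at -0.79 ± 0.05 and MSMO1 at -0.70 ± 0.05. For cholesterol genes camera gave an adjusted p of 0.000548 (adjusted p = 0.439 with an estimated correlation). In the replication list 21 of 28 genes fell and 1 rose, 22 and 1 adjusted over the list alone, with a median of -0.33. CLSPN, a checkpoint mediator, fell by 0.69 ± 0.05 and the polymerase subunit POLE by 0.58 ± 0.05, and the helicase subunit MCM6 rose by 0.47 ± 0.06. The replication list had a camera adjusted p of 1.19e-06 (adjusted p = 0.439 with an estimated correlation). Targets of MondoA, a glucose-sensing transcription factor, had 6 of 7 members lower and none higher, or 6 and 1 adjusted over the list alone, among them PFKFB3 (-0.60 ± 0.04), KLF10 (-0.92 ± 0.08) and TXNIP (-0.90 ± 0.14). For these the camera test gave an adjusted p of 0.00823 (adjusted p = 0.276 with an estimated correlation). Of 16 cytosolic heat shock genes 8 fell and none rose, 9 adjusted over the list alone, including HSPA8 (-0.48 ± 0.06) and HSPH1 (-0.51 ± 0.07), with a camera adjusted p of 0.036 (adjusted p = 0.784 with an estimated correlation). That call ended in 3 of the 12 fits with 1 library left out, at most without OGDH-deficient control replicate 2 (adjusted p = 0.0939).

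Lysosomal, ribosomal protein, interferon-stimulated and YAP target genes were higher. Of 27 autophagy and lysosome genes 17 rose and 1 fell, over all genes and over the list alone, among them the proteases CTSB (1.09 ± 0.04) and CTSD (0.80 ± 0.07) and the membrane glycoprotein GPNMB (0.60 ± 0.04). For lysosomal genes camera gave an adjusted p of 0.000395 (adjusted p = 0.402 with an estimated correlation). Of 38 cytosolic ribosomal protein genes 27 rose and none fell, 29 adjusted over the list alone, with small changes such as RPLP0 at 0.26 ± 0.04. Ribosomal proteins had a camera adjusted p of 3.6e-05 (adjusted p = 0.784 with an estimated correlation). Among 18 interferon-stimulated genes 9 rose and none fell, on both counts, including IFIT3 (1.34 ± 0.13, 5.12 to 12.96 CPM) and BST2 (1.23 ± 0.21, 2.13 to 4.99 CPM). Interferon-stimulated genes had a camera adjusted p of 0.00425 (adjusted p = 0.276 with an estimated correlation). YAP and TEAD targets had 9 of 16 members higher and 2 lower, on both counts, led by the matricellular protein gene CCN1 at 1.97 ± 0.06 (368.1 to 1441 CPM) and by ANKRD1 at 1.25 ± 0.07. YAP targets had a camera adjusted p of 0.027 (adjusted p = 0.593 with an estimated correlation). In the list of 2-oxoglutarate and glutamine metabolism 11 of 20 genes rose and 3 fell, 11 and 4 over the list alone, PSAT1 rising and the glutamine transporter SLC38A2 falling by 1.13 ± 0.05. This metabolic list had a camera adjusted p of 0.0395 (adjusted p = 0.691 with an estimated correlation). Its call ended without WT control replicate 2 (adjusted p = 0.0502).

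Other strongly raised genes were the snoRNA SNORD5 (2.67 ± 0.12), SEL1L3 (1.98 ± 0.07), the snoRNA SNORA8 (1.94 ± 0.12), the ankyrin gene ANK2 (1.88 ± 0.10) and MRFAP1L1 (1.82 ± 0.06). Both snoRNAs lie inside other genes, and mRNA libraries catch such short RNAs poorly, so their values are uncertain. The septin SEPTIN2 (1.37 ± 0.04, 150.6 ± 1.86 to 388.0 ± 5.98 CPM), NIBAN1, a stress-induced gene (1.61 ± 0.05), SERINC1 (1.55 ± 0.05) and C5orf15 (1.55 ± 0.05) had the smallest p among rising genes with a mean CPM of at least 5 (edgeR adjusted p at most 3.93e-15). PRAME, a melanoma antigen, had a log2 fold change of 1.83 ± 0.59 with scattered libraries (2.66 ± 1.16 against 9.41 ± 6.23 CPM, edgeR adjusted p = 0.0167), and its call ended without any of 3 single libraries, at most without OGDH-deficient control replicate 1 (1.16, adjusted p = 0.148), and also with a robust spread estimate and with DESeq2 (adjusted p = 0.133 and 0.126). Over all genes, 8247 of 18781 (43.9%) were called, 4180 higher and 4067 lower, of which 1303 changed by a log2 of more than 1 (354 higher, 949 lower). Camera called 13 of 42 lists, 6 higher and 7 lower. With the correlation estimated from the data 0 lists were called in this and in every other comparison (smallest adjusted p = 0.276; 4 lists at an unadjusted p under 0.05), and fry, which tests whether the genes of a list move 1 way on balance without comparing them with other genes, called 30. No called list of any comparison had a median, mean and test that differed in sign.

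**Figure D2:**
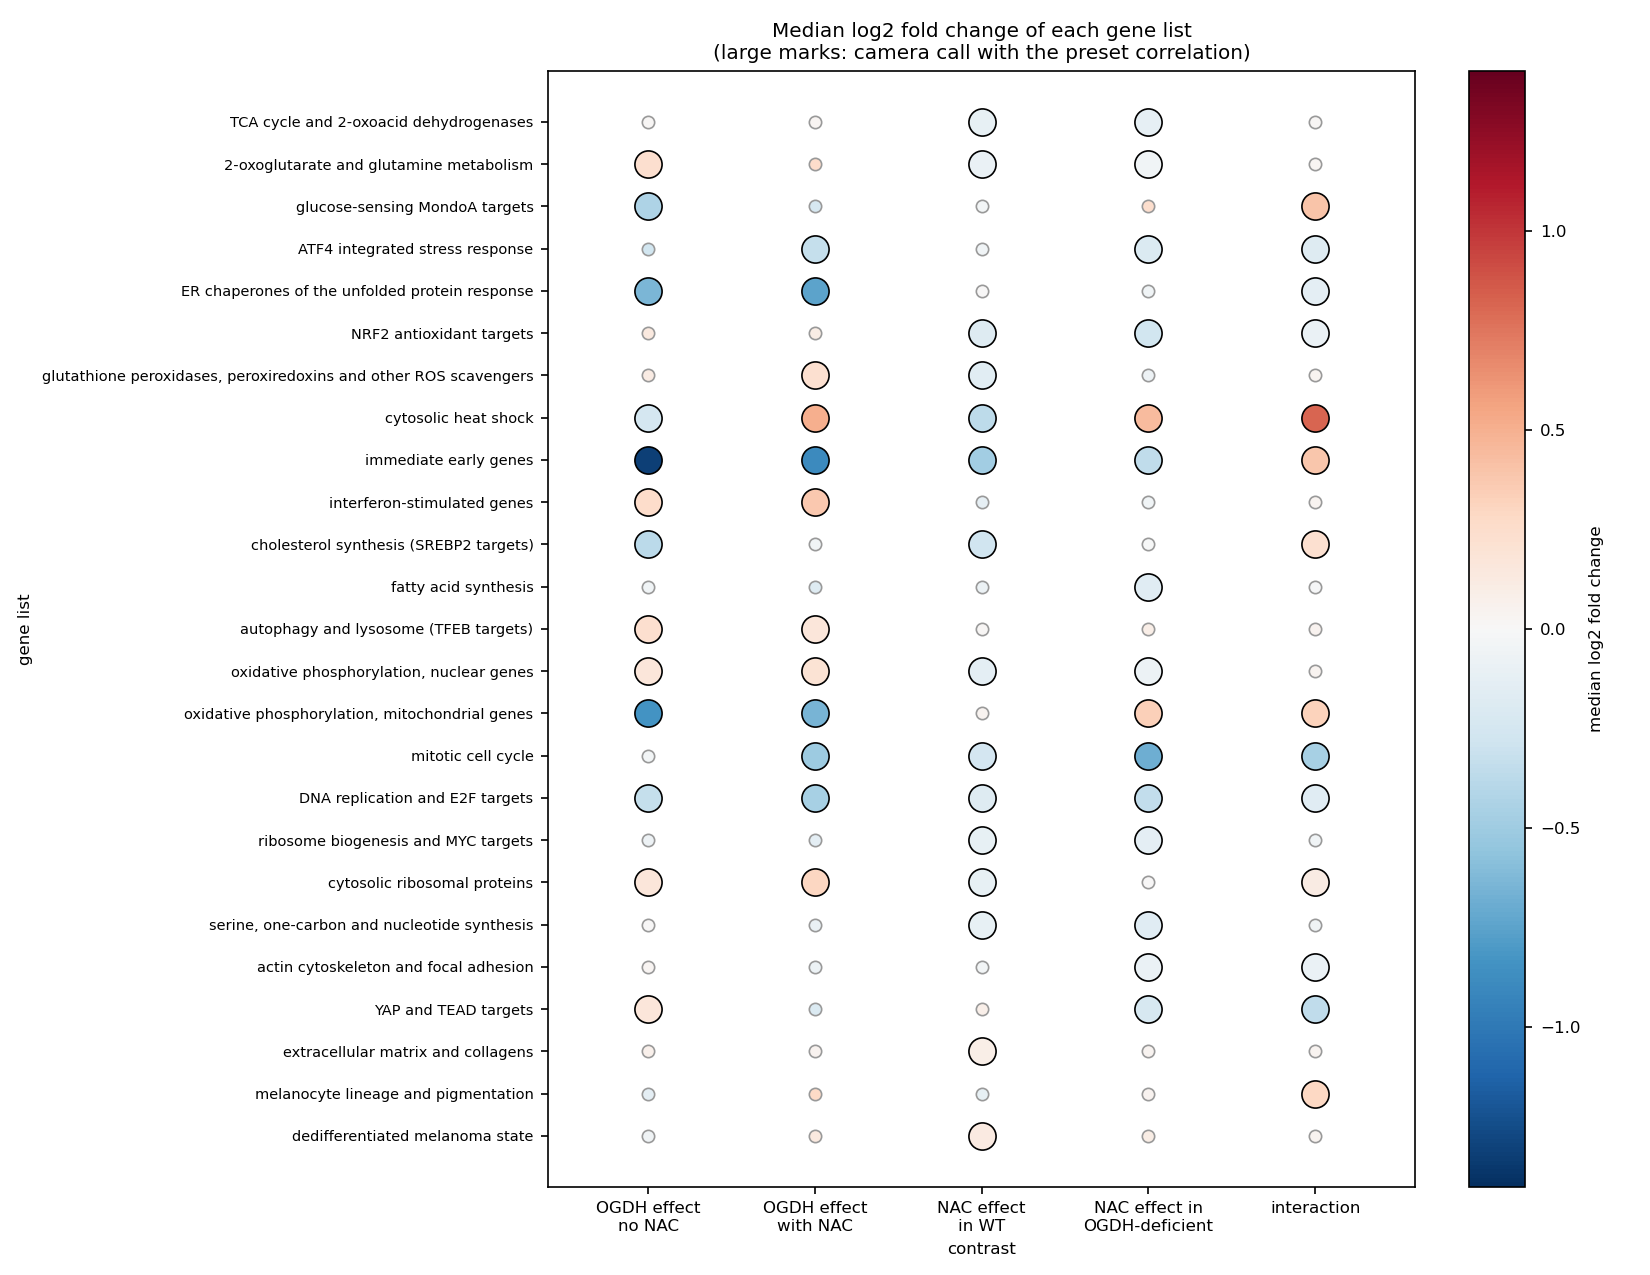
Median log2 fold change of the gene lists called in at least 1 comparison (vertical axis: list; horizontal axis: comparison; colour: median log2 fold change; large outlined marks: camera adjusted p under 0.05 with the preset correlation, none of which held with an estimated correlation). ER chaperones and mRNAs of the mitochondrial genome are low in both OGDH comparisons (medians -0.64 and -0.75, and -0.84 and -0.66), and heat shock and mitotic genes have interaction medians of 0.82 and -0.46.

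The same genotype comparison was made in cells given NAC. ER stress genes were again lower: 18 of 20 fell and 1 rose, 18 and 2 adjusted over the list alone, with a median of -0.75. HERPUD1 fell by 2.78 ± 0.05, HSPA5 by 1.67 ± 0.06 and XBP1 by 1.55 ± 0.06. ER chaperones had a camera adjusted p of 9.52e-10 (adjusted p = 0.434 with an estimated correlation). HMOX1 fell by 4.80 ± 0.18 from 1171 ± 77.8 to 42.3 ± 17 CPM, CHAC1 by 3.74 ± 0.10 and DDIT4 by 3.15 ± 0.09 (edgeR adjusted p at most 2.24e-15 for CHAC1 and DDIT4, 4.98e-14 for HMOX1). In the ATF4 list 19 of 34 fell and 9 rose, 20 and 9 over the list alone, with a median of -0.33. Beside DDIT3 (-2.78 ± 0.06) and the leucine sensor SESN2 (-2.26 ± 0.06) the cystine transporter SLC7A11 fell by 1.34 ± 0.07. The ATF4 list had a camera adjusted p of 0.0137 (adjusted p = 0.522 with an estimated correlation). Immediate early genes again had 15 of 20 members lower and 3 higher, on both counts, with DUSP1 at -1.38 ± 0.06 and MYC at 0.90 ± 0.05. The early gene list had a camera adjusted p of 0.000367 (adjusted p = 0.61 with an estimated correlation).

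Cell cycle genes were lower in OGDH-deficient cells with NAC. Of 23 mitotic genes 22 fell and 1 rose, on both counts, with a median of -0.51. The kinesin KIF20A fell by 0.94 ± 0.06, the anaphase activator CDC20 by 0.87 ± 0.05, the kinase PLK1 by 0.87 ± 0.06 and the proliferation marker MKI67 by 0.82 ± 0.05, and the survivin gene BIRC5 rose by 0.28 ± 0.05. The mitotic list had a camera adjusted p of 2.16e-08 (adjusted p = 0.505 with an estimated correlation). Of 28 replication genes 25 fell and none rose, on both counts, among them POLE (-0.95 ± 0.05) and CDC6, which loads the replicative helicase (-0.84 ± 0.06). Replication genes as a list had a camera adjusted p of 9.52e-10 (adjusted p = 0.434 with an estimated correlation). Mitochondrial mRNAs had 11 of 13 members lower and 1 higher, on both counts, with a median of -0.66, including MT-ND1 (-1.498 ± 0.13) and MT-ND2 (-0.70 ± 0.05). The list of these mRNAs had a camera adjusted p of 0.0017 (adjusted p = 0.61 with an estimated correlation). The mitochondrial ribosomal RNAs, which are not in this list, were higher, MT-RNR2 by 0.78 ± 0.05 and MT-RNR1 by 0.42 ± 0.08 (edgeR adjusted p = 3.41e-10 and 0.000117). The mitochondrial share of counts was 4.20 ± 0.0745% in WT and 3.50 ± 0.698% in OGDH-deficient cells (exact two-sided permutation p = 0.3). The deficient libraries held 3.43% (95% Wilson interval 3.42 to 3.43), 4.24% (4.23 to 4.24) and 2.85% (2.84 to 2.85), in replicates 1, 2 and 3.

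Heat shock genes were higher in this comparison: 15 of 16 rose and none fell, 16 adjusted over the list alone, with a median of 0.51, led by the small chaperone HSPB1 at 1.39 ± 0.09 (178.7 ± 9.27 to 467.7 ± 96.4 CPM) and HSP90AA1 at 0.67 ± 0.07. The heat shock list had a camera adjusted p of 0.000487 (adjusted p = 0.61 with an estimated correlation). HSPA1A rose by 1.22 ± 0.16, and its reads are shared with the near-identical HSPA1B. Of 38 ribosomal protein genes 33 rose and none fell, on both counts, with RPS16 at 0.46 ± 0.05. As a list they had a camera adjusted p of 4.03e-07 (adjusted p = 0.61 with an estimated correlation). Nuclear oxidative phosphorylation genes (24 of 38 higher, 2 lower) with COX7A2 at 0.45 ± 0.05, lysosomal genes (17 of 27 higher, 5 lower) with CTSB at 1.17 ± 0.04 and GPNMB at 1.23 ± 0.04, and interferon-stimulated genes (10 of 18 higher, none lower) rose too, with equal counts adjusted over the list alone. In that order they had a camera adjusted p of 0.000674, 0.00184 and 0.0125 (adjusted p = 0.61, 0.505 and 0.434 with an estimated correlation). Peroxidases and other scavengers of reactive oxygen had 11 of 18 members higher and 1 lower, on both counts, with SOD1 at 0.24 ± 0.04 (camera adjusted p = 0.0482; adjusted p = 0.61 with an estimated correlation). That call ended in 8 of the 12 fits with 1 library left out, at most without OGDH-deficient NAC replicate 3 (adjusted p = 0.0843), and with RLE scaling (adjusted p = 0.0668).

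Single genes that rose included SEL1L3 (2.64 ± 0.07), SNORD5 (2.48 ± 0.11), the collagen COL6A3 (2.30 ± 0.09, 9.67 ± 1.28 to 47.6 ± 4.10 CPM), the adhesion gene NEGR1 (2.28 ± 0.14), TAGLN3 (2.11 ± 0.11) and GAS1 (2.07 ± 0.16). SCAMP3 had a value of 2.21 ± 0.75 (edgeR adjusted p = 0.0188), and that call ended without any of 3 single libraries, at most without WT NAC replicate 3 (1.69, adjusted p = 0.0824), while without WT NAC replicate 1 the value was 4.92 (adjusted p = 0.000215). With a robust spread estimate and with DESeq2 the SCAMP3 call ended too (adjusted p = 0.14 and 0.154). NIBAN1 (1.86 ± 0.05), SEPTIN2 (1.39 ± 0.04), PTMA (-1.78 ± 0.04) and ZNF469 (-2.51 ± 0.18) changed as without NAC in direction. In total 9809 genes (52.2%) were called, 5097 higher and 4712 lower, 1685 of them by a log2 of more than 1 (661 higher, 1024 lower). Without OGDH-deficient NAC replicate 2, 9650 genes were called. Camera called 12 lists, 6 each way (estimated correlation: 0 lists, smallest adjusted p = 0.434, with 3 at an unadjusted p under 0.05; fry: 28).

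Across all 18781 genes the OGDH effects with and without NAC, which share no library, correlated with r = 0.649 (simulated without effects: -0.002; covariance 0.286). Of 4180 genes higher without NAC 3205 (76.7%) were higher with NAC, against 1134 for independent lists, and of 4067 lower genes 2877 (70.7%) were lower, against 1020. Opposite calls were made for 93 and 117 genes, against 1049 and 1104.

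The third comparison asked what NAC did in WT cells. Cholesterol synthesis genes fell: 16 of 24 were lower and none higher, on both counts, with a median of -0.28, among them IDI1 (-0.68 ± 0.05), HMGCS1 (-0.59 ± 0.06) and the SREBP regulator INSIG1 (-0.60 ± 0.07). Camera for cholesterol genes gave an adjusted p of 5.4e-08 (adjusted p = 0.382 with an estimated correlation). Immediate early genes fell in 14 of 20 cases and none rose, 14 and 1 adjusted over the list alone, with JUN at -0.74 ± 0.07, EGR2 at -1.48 ± 0.13, EGR1 at -0.88 ± 0.10 and FOS at -1.60 ± 0.26 (283.0 ± 9.35 to 93.5 ± 15.7 CPM). Immediate early genes as a list had a camera adjusted p of 7.79e-06 (adjusted p = 0.382 with an estimated correlation). Mitotic genes had 18 of 23 members lower and none higher, 20 over the list alone, with BIRC5 at -0.42 ± 0.05 and AURKA at -0.51 ± 0.06, and replication genes 16 of 28, 21 over the list alone, with PCNA at -0.28 ± 0.05. Mitotic and replication genes had a camera adjusted p of 3.73e-08 and 1.31e-06 (adjusted p = 0.382 for both with an estimated correlation). Of 16 heat shock genes 13 fell and none rose, 14 over the list alone, with DNAJA1 at -0.48 ± 0.07 and HSPH1 at -0.45 ± 0.07. Heat shock genes as a list had a camera adjusted p of 1.88e-05 (adjusted p = 0.394 with an estimated correlation).

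Antioxidant genes also fell by small amounts. Of 26 NRF2 targets 11 fell and 2 rose, 12 and 2 over the list alone, with TXN at -0.24 ± 0.04, GCLM at -0.31 ± 0.06 and NQO1 at -0.21 ± 0.04, and HMOX1 had a value of -0.07 ± 0.15 that did not pass. NRF2 targets as a list had a camera adjusted p of 0.00143 (adjusted p = 0.382 with an estimated correlation). Of 18 reactive oxygen scavengers 13 fell and none rose, on both counts, with SOD1 at -0.34 ± 0.04. Scavengers as a list had a camera adjusted p of 0.000392 (adjusted p = 0.382 with an estimated correlation). Metabolic lists were lower by medians between -0.10 and -0.14 (-0.076 for the serine list without WT NAC replicate 2). In these, 10 of 23 TCA cycle genes fell (13 over the list alone), 7 of 20 in 2-oxoglutarate and glutamine metabolism (8), 16 of 38 nuclear oxidative phosphorylation genes (19), 10 of 19 in serine, one-carbon and nucleotide synthesis (10) and 13 of 38 ribosomal protein genes (15), and none rose except 1 of the serine list over the list alone. PSAT1 (-0.22 ± 0.04) and CYCS (-0.31 ± 0.04) were among them. In the order given they had a camera adjusted p of 0.00312, 0.00731, 9.68e-06, 0.00393 and 0.000114 (adjusted p = 0.382 for the first 4 and 0.577 for ribosomal proteins with an estimated correlation). Ribosome biogenesis and MYC targets had 12 of 24 members lower and 1 higher on both counts. MYC targets as a list had a camera adjusted p of 0.00385 (adjusted p = 0.382 with an estimated correlation).

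Matrix genes rose in 10 of 27 cases and 1 fell, on both counts, with fibronectin FN1 at 0.63 ± 0.06 and the collagen COL5A1 at 0.68 ± 0.09. Matrix genes as a list had a camera adjusted p of 0.0345 (adjusted p = 0.631 with an estimated correlation). Markers of the dedifferentiated melanoma state rose in 7 of 16 cases, with the receptor tyrosine kinase AXL at 0.46 ± 0.04, and 1 fell, or 7 and 2 over the list alone. Markers of this state had a camera adjusted p of 0.0472 (adjusted p = 0.382 with an estimated correlation). The matrix call ended in 2 and the melanoma state call in 6 of the 12 fits with 1 library left out, at most without WT NAC replicate 2 (adjusted p = 0.26) and without WT control replicate 2 (adjusted p = 0.135). The matrix median of 0.09 was 0.04 and 0.16 without WT NAC replicates 2 and 3, and fry did not call this list (adjusted p = 0.0942).

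Single genes that fell included RASD1, a Ras-related GTPase gene (-3.56 ± 0.17, 16.1 ± 1.31 to 1.36 ± 0.103 CPM), the transcriptional inhibitor ID2 (-2.42 ± 0.10, 60.1 ± 1.39 to 11.2 ± 1.98 CPM), the epithelial-mesenchymal transition factor SNAI1 (-1.14 ± 0.06), the phosphatase DUSP2 (-1.06 ± 0.14) and the cytokine signalling inhibitor SOCS3 (-0.999 ± 0.07) (edgeR adjusted p from 9.51e-12 to 1.89e-05). GTPBP6 had a value of -1.16 ± 0.31; its symbol lies on 2 chromosomes and its call ended without WT control replicate 1 (adjusted p = 0.0533), with a robust spread estimate (0.0951) and with DESeq2 (0.0566), and its value was -0.74 without WT NAC replicate 2. ZNF469 rose by 1.96 ± 0.18 (9.21 ± 0.850 to 35.8 ± 2.85 CPM) and the cytokine CSF2 by 1.20 ± 0.17. The inhibin and activin subunit INHBA also rose, by 0.76 ± 0.05 (163.0 ± 3.70 to 275.5 ± 17.8 CPM) and the nuclear RNA NEAT1 by 0.76 ± 0.05. IGSF9B rose by 1.18 ± 0.12, the miRNA host genes MIR34AHG and MIR3142HG by 1.24 ± 0.14 and 1.15 ± 0.11, CREBZF by 0.58 ± 0.04 and VMP1, an autophagy gene, by 0.56 ± 0.04. The antisense genes STARD4-AS1 (1.54 ± 0.18) and ALDH1A3-AS1 (1.30 ± 0.12) are uncertain, since counting ignored strand. In total 4835 genes (25.7%) were called, 2246 higher and 2589 lower, 597 of them by a log2 of more than 1 (478 higher, 119 lower). With library size in place of TMM the share of higher calls was 66.2% instead of 46.5%. Camera called 15 lists, 2 higher and 13 lower (estimated correlation: 0 lists, smallest adjusted p = 0.382, with 2 at an unadjusted p under 0.05; fry: 23).

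The fourth comparison asked what NAC did in OGDH-deficient cells. All 23 mitotic genes fell, on both counts, with a median of -0.69. KIF20A fell by 1.25 ± 0.06 from 84.3 ± 1.52 to 35.4 ± 2.77 CPM, PLK1 by 1.17 ± 0.06, AURKA by 1.11 ± 0.06 and CCNB1, the mitotic cyclin, by 0.95 ± 0.05 (edgeR adjusted p at most 2.08e-10). Mitotic genes as a list had a camera adjusted p of 2.6e-18 (adjusted p = 0.214 with an estimated correlation). Replication genes fell in 27 of 28 cases and none rose, on both counts, with MCM6 at -0.84 ± 0.06 and PCNA at -0.64 ± 0.05. The replication genes had a camera adjusted p of 6.59e-12 (adjusted p = 0.214 with an estimated correlation). NRF2 targets fell in 17 of 26 cases and 2 rose, 18 and 3 over the list alone, with a median of -0.27. GCLM, a subunit of the glutathione-synthesizing ligase, fell by 1.57 ± 0.06, thioredoxin reductase TXNRD1 by 1.39 ± 0.04 (2074 ± 58.6 to 793.0 ± 37.6 CPM), SLC7A11 by 0.99 ± 0.07 and HMOX1 by 0.88 ± 0.17. Without NAC, TXNRD1 had been higher in OGDH-deficient libraries (2036 to 2141 CPM) than in WT libraries (1312 to 1385 CPM), unlike HMOX1. The NRF2 list had a camera adjusted p of 4.52e-05 (adjusted p = 0.372 with an estimated correlation). ATF4 targets fell in 20 of 34 cases and 2 rose, 21 and 2 over the list alone, among them the amino acid transporters SLC7A5 (-0.61 ± 0.06) and SLC7A1 (-0.53 ± 0.05), while DDIT3 (0.13 ± 0.07) and CHAC1 (-0.14 ± 0.12) did not pass. ATF4 targets as a list had a camera adjusted p of 0.000172 (adjusted p = 0.214 with an estimated correlation).

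Mitochondrial transcripts were higher: MT-RNR2 rose by 2.43 ± 0.06 from 776.5 ± 68.8 to 4173 ± 243.0 CPM, MT-RNR1 by 1.95 ± 0.08 and MT-ND6 by 2.17 ± 0.20 (edgeR adjusted p = 3.1e-16, 3.57e-12 and 9.44e-08). Of the 13 mitochondrial mRNAs 7 rose, among them MT-CO1 (1.5 ± 0.15), and 1 fell, MT-ND2 (-0.26 ± 0.05), or 7 and 2 over the list alone. Mitochondrial mRNAs as a list had a camera adjusted p of 0.0211 (adjusted p = 0.648 with an estimated correlation). The mitochondrial share of counts rose by 1.45 points, from 2.05 to 3.50% (exact two-sided permutation p = 0.1, the smallest possible), and was highest in the outlying replicate 2, without which the list was not called (median 0.23, adjusted p = 0.119). Heat shock genes rose in 12 of 16 cases and none fell, 13 over the list alone, with HSPA4L at 0.66 ± 0.08 and HSPB1 at 0.71 ± 0.09. Heat shock genes together had a camera adjusted p of 0.000363 (adjusted p = 0.588 with an estimated correlation).

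**Figure D3:**
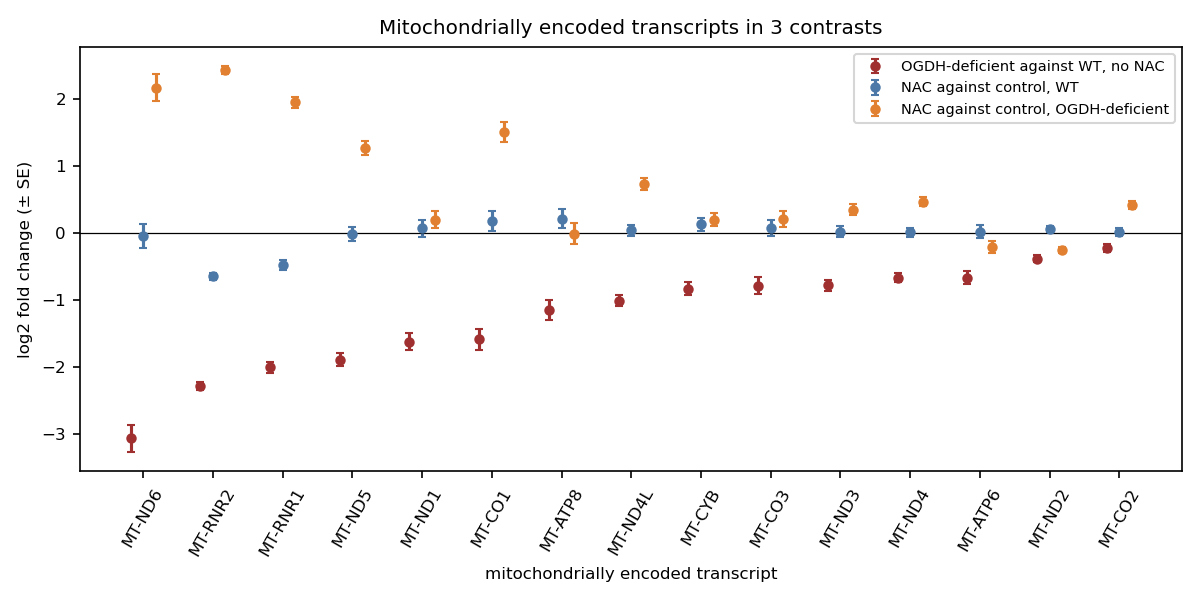
Log2 fold changes of the 15 mitochondrial mRNAs and ribosomal RNAs (horizontal axis: transcript; vertical axis: log2 fold change; bars: SE derived from the edgeR F statistic, with a spread estimate shared by all groups, 3 libraries per group) for OGDH deficiency without NAC and for NAC in each genotype. All 15 are below 0 for OGDH deficiency, with a median of -1.01, and MT-RNR2 rises by 2.43 with NAC in OGDH-deficient cells and has a value of -0.65 with NAC in WT cells.

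Several other lists were lower with NAC in OGDH-deficient cells. Fatty acid synthesis genes fell in 7 of 12 cases and none rose, on both counts, with a median of -0.17. Fatty acid genes had a camera adjusted p of 0.0173 (adjusted p = 0.214 with an estimated correlation). Serine, one-carbon and nucleotide synthesis genes fell in 12 of 19 cases and 2 rose, 13 and 2 over the list alone, with PSAT1 at -0.55 ± 0.04. Serine synthesis genes had a camera adjusted p of 0.00177 (adjusted p = 0.372 with an estimated correlation). Genes of 2-oxoglutarate and glutamine metabolism (9 of 20 lower, none higher, on both counts) with SLC38A2 at -0.55 ± 0.05, actin cytoskeleton genes (10 of 23 lower, 2 higher, or 11 and 3 over the list alone) and ribosome biogenesis genes (13 of 24 lower, 2 higher, or 13 and 3) fell as well, although MYC itself rose by 0.74 ± 0.05. The 3 lists had a camera adjusted p of 0.0159, 0.0173 and 0.0159 (adjusted p = 0.528, 0.336 and 0.547 with an estimated correlation). YAP targets fell in 8 of 16 cases and 3 rose, on both counts, with the LIM protein AJUBA at -1.10 ± 0.05 and AMOTL2 at -0.81 ± 0.05 (camera adjusted p = 0.038; adjusted p = 0.547 with an estimated correlation). That call ended in 2 fits, at most without OGDH-deficient NAC replicate 3 (adjusted p = 0.0654). TCA cycle genes (10 of 23 lower, 1 higher, or 11 and 1), nuclear oxidative phosphorylation genes (11 of 38 lower, none higher, or 9 over the list alone) and immediate early genes (10 of 20 lower, 3 higher, or 10 and 4) were called with camera adjusted p = 0.0189, 0.0173 and 0.0474 (adjusted p = 0.588, 0.648 and 0.648 with an estimated correlation). Without the outlying replicate 2 these 3 calls ended (adjusted p = 0.0808, 0.197 and 0.197), and with RLE scaling that of immediate early genes (adjusted p = 0.0546).

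Other named genes that fell were ID2 (-1.78 ± 0.12), the cytokine IL6 (-1.76 ± 0.11, 26.8 ± 0.685 to 7.89 ± 1.01 CPM), the calcium-binding protein gene CALB2 (-1.76 ± 0.08), ART3 (-1.70 ± 0.15), MYPN (-1.52 ± 0.14) and the homeobox gene HHEX (-1.22 ± 0.05). Genes that rose included AHNAK2 (1.72 ± 0.11), MIR17HG, host of the miR-17-92 cluster (1.63 ± 0.11), GAS1 (1.54 ± 0.15), the arrestin-domain gene ARRDC3 (1.43 ± 0.07), and RASAL2, a RasGAP gene (1.003 ± 0.05). In total 7158 genes (38.1%) were called, 3623 higher and 3535 lower, 1083 of them by a log2 of more than 1 (846 higher, 237 lower), and 6559 were called without replicate 2. Camera called 15 lists, 2 higher and 13 lower (11 lists without replicate 2; estimated correlation: 0 lists, smallest adjusted p = 0.214, with 5 at an unadjusted p under 0.05; fry: 31).

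The NAC effects in both genotypes, which share no library, correlated with r = 0.466 (simulated without effects: -0.002; covariance 0.131). Of 2246 genes higher with NAC in WT cells 1283 were higher in OGDH-deficient cells, against 433.3 for independent lists, and of 2589 lower genes 1375 were lower, against 487.3.

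Whether the NAC effect differed between genotypes was tested by the interaction. Mitotic genes fell further with NAC in OGDH-deficient cells: 22 of 23 had a negative interaction and none a positive one, on both counts, with a median of -0.46. They were led by KIF20A (-0.84 ± 0.08) and PLK1 (-0.86 ± 0.09). Together the mitotic genes had a camera adjusted p of 1.24e-15 (adjusted p = 0.339 with an estimated correlation). Heat shock genes had opposite NAC effects in the 2 genotypes. Of these, 14 of 16 had a positive interaction and none a negative one, 16 over the list alone, with a median of 0.82, including HSPH1 (1.02 ± 0.10) and HSPB1 (1.18 ± 0.13). Together the heat shock genes had a camera adjusted p of 3.96e-11 (adjusted p = 0.37 with an estimated correlation). Cholesterol genes had a positive interaction in 10 of 24 cases, 11 over the list alone, and a negative one in none, with INSIG1 at 0.97 ± 0.10 and MSMO1 at 0.75 ± 0.08. Cholesterol genes as a list had a camera adjusted p of 2.92e-05 (adjusted p = 0.37 with an estimated correlation). YAP targets (10 of 16 negative, 1 positive, or 13 and 2) with AJUBA at -0.93 ± 0.07, ATF4 targets (13 of 34 negative, 2 positive, or 16 and 3) with SLC7A11 at -1.19 ± 0.10, and replication genes (10 of 28 negative, none positive, or 13) with MCM6 at -0.73 ± 0.09 were lower. In this order they had a camera adjusted p of 2.24e-05, 0.000244 and 7.82e-05 (adjusted p = 0.339, 0.339 and 0.491 with an estimated correlation).

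Among called genes with a gene name and a mean CPM of at least 5, the highest interaction values were those of MT-RNR2 (3.08 ± 0.08), MT-RNR1 (2.43 ± 0.11), MT-ND6 (2.21 ± 0.27), IER5L (1.63 ± 0.25) and HSPA1A (1.62 ± 0.22), and the lowest those of CALB2 (-1.64 ± 0.11), IL6 (-1.59 ± 0.15), the polarity gene SCRIB (-1.52 ± 0.33), the pseudogene NMRAL2P (-1.51 ± 0.28) and MYPN (-1.45 ± 0.19) (edgeR adjusted p from 1.38e-15 to 0.00364). The SCRIB libraries were scattered (8.28 ± 4.12 CPM in WT control cells), and its call ended with a robust spread estimate (adjusted p = 0.0658). In total 2781 genes (14.8%) were called, 1384 with a positive and 1397 with a negative value (1159 and 1735 with library size in place of TMM), 331 of them beyond a log2 of 1 (217 and 114), and 3424 were called without OGDH-deficient NAC replicate 2. Camera called 14 lists, 7 each way, 10 without replicate 2 and 8 without WT control or WT NAC replicate 3 (estimated correlation: 0 lists, smallest adjusted p = 0.339, with 5 at an unadjusted p under 0.05; fry: 14).

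The design also asks whether NAC moved genes back toward the WT level. The NAC effect in OGDH-deficient cells and the OGDH effect without NAC share the 3 OGDH-deficient control libraries with opposite sign and correlated with r = -0.163, against -0.495 for simulated unchanged groups. Without OGDH-deficient control replicate 1, 2 or 3 the value was -0.311, -0.281 and -0.29. The covariance was -0.0616 against -0.0347 simulated. Of 4067 genes lower in OGDH-deficient cells 974 rose with NAC, against 784.6 for independent lists, and 1042 fell further, against 765.5. Of 4180 higher genes 905 fell, against 786.8, and 873 rose further, against 806.4. Counts in both directions exceeded those of independent lists, and the lists share libraries. They therefore cannot decide whether genes moved back. In the 10793 genes with a mean CPM of at least 5 the correlation was 0.007, against -0.5 simulated over these genes, and the covariance 0.000811 against -0.00371, so that the difference from the simulated covariance was 0.00452 there and -0.0269 over all genes. The OGDH effect without NAC and the NAC effect in WT cells, which share the WT control libraries, correlated with r = 0.222 (simulated 0.51; covariance 0.0686 against 0.0362 simulated), with 632 genes higher in both (499.9 for independent lists), 875 lower in both (560.6), 641 higher and then lower (576.2) and 554 lower and then higher (486.4). The 3 shared control libraries could not be split into sets of 2, so part of the excess may come from sharing.

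Lists of epithelial, haematopoietic, fibroblast and embryonic kidney or neuroendocrine genes were not called in any comparison (smallest camera adjusted p = 0.246). The test compares groups, so it does not show whether such cells are present in all of them. The fibroblast list also shares collagens with the matrix list. Replication-dependent histone genes, whose mRNAs lack poly-A tails, were not called either (17 tested, medians from -0.29 to 0.24).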

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

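The tests of dilution and of RNA tails for mitochondrial transcripts and of cycling cells for mitotic genes were chosen only after the result was seen. The results below stand out because the interaction test of edgeR called them, which means that the NAC effect differed between the genotypes. This holds for 87 of the 131 named genes (47 higher, 40 lower, edgeR adjusted p under 0.05), and for 14 of 42 lists by camera. Over all 18781 genes tested the share was 14.8%. Genes were named for extreme values or small p, in part in the interaction itself, so a high share among them follows from the choice.

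Positive values, where NAC acted upward in OGDH-deficient relative to WT cells, were found for mitochondrial transcripts beside MT-RNR2 (3.08), MT-RNR1 (2.43) and MT-ND6 (2.21): MT-CO1 had 1.32 and MT-ND5 1.28. Heat shock genes were HSPA1A (1.62), HSPB1 (1.18), DNAJB1 (1.09), HSPH1 (1.02), HSPA4L (0.84), DNAJA1 (0.79), HSPA8 (0.73), HSP90AA1 (0.71) and FKBP4 (0.41). Cholesterol genes were INSIG1 (0.97), MSMO1 (0.75), SQLE (0.27), HMGCS1 (0.26) and IDI1 (0.24), and immediate early genes FOS (1.13), MYC (0.67), JUN (0.35), JUNB (0.31) and KLF6 (0.20). Others were GAS1 (1.75), IER5L (1.63), DUSP2 (1.54), SNAI1 (1.25), ID2 (0.64), SOCS3 (0.36), NEGR1 (1.41), ARRDC3 (1.31), COL6A3 (1.06), TAGLN3 (1.02), OGDH (0.83), TXNIP (0.75), AHNAK2 (0.73), SEL1L3 (0.67), GPNMB (0.62), MIR17HG (0.61), KLF10 (0.49), RASAL2 (0.48), COL5A1 (0.43), NIBAN1 (0.24), RPS16 (0.22), SOD1 (0.20) and COX7A2 (0.20). Calls ended with 1 library left out in 11 of 12 fits for IDI1 (highest adjusted p = 0.133, without OGDH-deficient control replicate 1) and COX7A2 (0.15, without OGDH-deficient NAC replicate 3), 10 for FOS (value 0.62, 0.171, same library) and HMGCS1 (0.131, without OGDH-deficient control replicate 1), and 8 for SQLE (0.0984, same library), COL5A1 (0.102, without OGDH-deficient control replicate 3) and RPS16 (0.0991, without OGDH-deficient control replicate 2). They ended in 7 for SOCS3 and JUNB (0.0979 and 0.0997, without OGDH-deficient NAC replicate 1) and KLF6 (0.0973, without WT NAC replicate 3), 5 for JUN (0.0579, without OGDH-deficient control replicate 2) and SOD1 (0.0726, without WT NAC replicate 3), 2 for TXNIP (0.0565, without OGDH-deficient NAC replicate 1) and 1 for ID2 (0.0513, without OGDH-deficient NAC replicate 3). Values of IDI1 and HMGCS1 without OGDH-deficient NAC replicate 3 were 0.15 and 0.16. Calls also ended with a robust spread estimate for KLF10 (adjusted p = 0.0625), JUN (0.0582) and FOS (0.239; DESeq2 0.19), with library size alone for FOS (0.0542), KLF6 (0.0672), IDI1 (0.0523), SQLE (0.0572), COL5A1 (0.0539) and COX7A2 (0.0622), and with RLE scaling for COX7A2 (0.0629).

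Negative values were found for genes of the NRF2, ATF4 and glutamine lists, GCLM (-1.27), SLC7A11 (-1.19), TXNRD1 (-1.19), HMOX1 (-0.82), SLC7A5 (-0.79), SLC7A1 (-0.76), SLC38A2 (-0.49), ATF3 (-0.40, also an immediate early gene), PSAT1 (-0.33), NQO1 (-0.31) and SESN2 (-0.27). Cell cycle genes were PLK1 (-0.86), KIF20A (-0.84), MCM6 (-0.73), AURKA (-0.60), CCNB1 (-0.57), MKI67 (-0.54), POLE (-0.38), PCNA (-0.36), CDC20 (-0.30), BIRC5 (-0.27) and CDC6 (-0.25), and YAP targets AJUBA (-0.93), AMOTL2 (-0.65), ANKRD1 (-0.58) and AXL (-0.20). Others were CALB2 (-1.64), IL6 (-1.59), SCRIB (-1.52), NMRAL2P (-1.51), MYPN (-1.45), ART3 (-1.11), ALDH1A3-AS1 (-0.85), STARD4-AS1 (-0.80), HHEX (-0.66), NEAT1 (-0.35), MRFAP1L1 (-0.33), MT-ND2 (-0.31), VMP1 (-0.28) and CREBZF (-0.24). Calls ended with 1 library left out in 9 of 12 fits for STARD4-AS1 (highest adjusted p = 0.118, without WT control replicate 2), 7 for ATF3 (0.0937, without OGDH-deficient control replicate 3), 6 for CDC6 (0.112) and 5 for SESN2 (0.0774), both without OGDH-deficient control replicate 2, and 1 for AXL (0.0537, without WT control replicate 2). The calls of HMOX1, ATF3 and SCRIB ended with a robust spread estimate (adjusted p = 0.151, 0.166 and 0.0658), those of HMOX1 and ATF3 also with DESeq2 (0.0909 and 0.093), and that of STARD4-AS1 with halved counts (0.0536).

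Besides the 6 lists of the report (medians -0.46 for mitotic, 0.82 for heat shock, 0.22 for cholesterol, -0.36 for YAP, -0.18 for ATF4 and -0.17 for replication genes), camera called 8 lists. Mitochondrial mRNAs had 6 of 13 members higher and 1 lower, 7 and 1 adjusted over the list alone (median 0.33, camera adjusted p = 0.0388; adjusted p = 0.71 with an estimated correlation), and immediate early genes 8 of 20 higher and 3 lower, or 12 and 3 (0.39, 0.0459; adjusted p = 0.71 with an estimated correlation). MondoA targets had 3 of 7 higher, or 4 and 1 lower (0.40, 0.0439; adjusted p = 0.37 with an estimated correlation), melanocyte genes 2 of 14 higher on both counts (0.29, 0.0388; adjusted p = 0.398 with an estimated correlation) and ribosomal proteins 3 of 38 on both counts (0.11, 0.00847; adjusted p = 0.71 with an estimated correlation). ER chaperones had 4 of 20 lower, or 7 (-0.14, 0.0279; adjusted p = 0.708 with an estimated correlation), NRF2 targets 7 of 26 lower and 2 higher, or 8 and 2 (-0.088, 0.0227; adjusted p = 0.694 with an estimated correlation), and actin genes 6 of 23 lower, or 7 (-0.088, 0.0388; adjusted p = 0.376 with an estimated correlation). All 8 calls ended in some fits with 1 library left out: MondoA and immediate early genes in 8 (highest adjusted p = 0.105 without OGDH-deficient NAC replicate 2 and 0.152 without WT NAC replicate 1), melanocyte genes in 6 (0.0797, without OGDH-deficient NAC replicate 1; median 0.18 without WT NAC replicate 3), mitochondrial mRNAs in 4 (median 0.21, 0.217, without OGDH-deficient NAC replicate 2), ribosomal proteins in 4 (median 0.05, 0.207, without OGDH-deficient NAC replicate 3; median 0.07 without OGDH-deficient control replicate 2), ER chaperones in 3 (0.0682, without WT control replicate 3), NRF2 targets in 3 (median -0.03, 0.0871, without OGDH-deficient NAC replicate 2; medians -0.049 and -0.054 without WT control replicates 2 and 3, and -0.056 and -0.055 without WT NAC replicates 1 and 3) and actin genes in 2 (0.0819, without WT control replicate 2). The fry test did not call ER chaperones, immediate early genes, mitochondrial mRNAs or ribosomal proteins (adjusted p = 0.0993, 0.146, 0.174 and 0.199).

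All 15 mitochondrial mRNAs and ribosomal RNAs were lower in OGDH-deficient cells without NAC (median -1.01), and with NAC 9 rose and 1 fell in those cells (median 0.42, against 0.02 in WT cells). A smaller mitochondrial share that dilutes these transcripts alike is argued against by the SD of their log2 fold changes, 0.791, which is 8.52 times their median SE. For weaker recovery of all RNAs with short or no poly-A tails, 17 histone genes had a median of -0.13 (SD 0.642). In mRNA libraries, reads of histone genes may come from forms with tails, so this median cannot decide the question. Among the 15 mitochondrial RNAs, MT-ND6, MT-RNR2 and MT-RNR1 fell most (-3.07, -2.29 and -2.01). The same RNAs rose most with NAC in OGDH-deficient cells (2.17, 2.43 and 1.95). In WT cells NAC lowered MT-RNR2 and MT-RNR1 (-0.649 and -0.485), and MT-ND6 was not called (-0.048). Tail length was not measured, so weaker recovery of RNAs with short or no tails, or of mitochondrial RNAs alone, is not excluded. Changed synthesis or decay of single mitochondrial transcripts with OGDH status and NAC may account for the pattern and was not tested.

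Mitotic genes had a median interaction of -0.46. The outlying OGDH-deficient NAC replicate 2 alone is argued against by a median of -0.44 without it (-0.436). A general fall of genes of cycling cells by equal amounts is argued against as the whole cause by the replication list. Its median of -0.172 differed from that of the mitotic list by -0.29 (permutation of list membership, 1e+05 permutations, p = 3e-05, across genes, which are not independent). A general fall of unequal size in the 2 lists was not tested and is not excluded. A delay at 1 phase of the cell cycle with NAC in OGDH-deficient cells could underlie the difference and was not tested.

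For each comparison of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05, and only 1 split, the real one, called as many genes: 8247, 9809, 4835 and 7158 by edgeR. The highest other split called 0 in each, and at an unadjusted p under 0.05 at most 512, 1019, 718 and 1246, against 9534, 10790, 6950 and 8605. For the interaction, 5 of 100 drawn permutations of NAC within genotype, of 200 distinct ones, called at least the real 2781 genes, the highest 3377. Apart from the real one, the other 4 keep or fully swap the NAC labels of 1 genotype, as did 17 drawn permutations, so a NAC effect common to both genotypes enters their interaction and the count does not bear on chance. Those that mixed both genotypes called at most 1. The permutation that swaps NAC in 1 genotype, which was not drawn, called 7964 genes. It tests the sum of the NAC effects of both genotypes, so that count does not bear on chance either.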

How the results depend on the processing

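Halved counts, leaving out libraries for the correlations and their simulation over genes with a mean CPM of at least 5 were chosen after the data were seen. Over 313 results of genes named in the text and all settings, calls were the same in 6544 cases, gained in 33, lost in 160 and reversed in 0, and over 69 list results the same in 957 and lost in 147. With 1 library left out, genes called ran from 7266 to 8738 and 8857 to 9743 for OGDH without and with NAC, 3602 to 5363 and 6053 to 7294 for NAC in WT and OGDH-deficient cells, and 2154 to 3424 for the interaction; OGDH itself ran from -3.94 to -3.80 and -3.13 to -2.95. Beyond a log2 of 1 the counts were 1303, 1685, 597, 1083 and 331, since fewer genes pass. Camera with an estimated correlation called 0 lists in each comparison (4, 3, 2, 5 and 5 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, 30, 28, 23 and 31. Interaction lists ran from 8 (without WT control or WT NAC replicate 3) to 14. The cause was not tested.

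At a mean CPM of at least 5 the correlations were 0.799 for OGDH with and without NAC, 0.514 for NAC in both genotypes, 0.007 (reversed in sign; -0.5 simulated for unchanged groups) for NAC in OGDH-deficient cells against OGDH, and 0.137 (0.499 simulated) for OGDH against NAC in WT cells. Over all genes, with 1 library left out, the correlations ran from 0.596 to 0.622, 0.401 to 0.451, -0.311 to -0.139 and 0.200 to 0.309. The cause was not tested.

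Replicate numbers did not pair the samples: deviations correlated from -0.047 to 0.023 for the same number and from -0.034 to 0.049 for others, and 1 of 12 libraries correlated best with its own number. With the number as a block 8128, 9689, 4649, 6994 and 2651 genes and 13, 11, 14, 14 and 12 lists were called, and OGDH values were -3.87, -3.04, -0.31, 0.51 and 0.83. Of the results named in the text, calls of 2 genes and 5 lists ended with the block (adjusted p from 0.0522 to 0.0674), and that of 1 gene was gained. Counting both mates and a depth of 31765845 to 37554200 counts limit values of genes near the floor, such as RASD1.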

Other observations

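The search for words highest in OGDH-deficient cells and the sequence set beside it were chosen only after the result was seen. Lists that camera called in no comparison included glycolysis, where 7 of 22 genes fell and 1 rose without NAC and 12 fell and 3 rose with NAC in OGDH-deficient against WT cells, equal to the counts adjusted over the list alone (camera adjusted p = 0.177 and 0.0881). Of 19 HIF targets 9 fell and 5 rose without NAC, 9 and 6 over the list alone (adjusted p = 0.541). Of 20 chromatin demethylases that use 2-oxoglutarate, the substrate of OGDH, 8 fell and 6 rose, 8 and 7 over the list alone (median 0.03, adjusted p = 0.944).

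Across 9927 genes with an annotated 3′ untranslated region (88.4% of those above a mean log2 CPM of 2), 15713 words of 7 bases were scanned. The word highest in both OGDH comparisons was GTGTCAC, with z = 9.69 without and 7.61 with NAC, and 1.01 and -0.35 for NAC in WT and OGDH-deficient cells; 30% of the 200 genes raised most without NAC carried it (23% with NAC), 12.9% of all genes called higher without NAC (11.4% with NAC) and 10.6% of all genes, with a log2 shift of 0.13. A candidate explanation is silencing of such transcripts in WT cells by a control reagent, which stays open. The reagent is not given in the sources used here, and z with NAC fell short of the limit set for it. A property of the genes wherever the word lies is not excluded either, with z of 3.91 and 3.07 in coding sequence. As background, TTCTCCGAACGTGTCACGT, a nontargeting sequence in common use written from memory after the word was seen, holds it at bases 11 to 17. Of the 22 words of both strands that were scanned, those other than GTGTCAC had z from -1.86 to 4.21 (GTCACGT) without NAC and from -2.06 to 3.69 (TCGGAGA) with NAC, with 1.72 and 1.35 for CGTGTCA and 3.36 and 2.17 for TGTCACG. Overlapping words that are not on the sequence had higher z without NAC, TGTCACT at 5.64, TGTGTCA at 5.27 and TGTCACA at 4.71. They share bases with GTGTCAC, so their values cannot decide for or against the sequence, which is not shown to be the source.

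Among genes lower in OGDH-deficient cells the word lowest by the weaker of its z in both comparisons was TTTTTGT, with z = -6.34 and -6.12, carried by 48.0% of all genes. In single comparisons GAACCAA was lowest without NAC (-7.28) and TATTTTT with NAC (-7.27). Silencing of other transcripts by the reagent against OGDH stays open, since no word reached the limit set beforehand in both, and GAACCAA had -5.86 with NAC. AGAACCA, which overlaps GAACCAA, had -5.99 without and -6.21 with NAC. In coding sequence AGAACCA was the lowest word in both comparisons (-6.48 and -5.78), and its sites in OGDH were not counted. TTTTTGT has 0 sites in the coding sequence and 0 in the 3′ untranslated region of OGDH, which a reagent with this seed against these parts would need, and GAACCAA has 1 in the coding sequence.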
